A study of Vitis vinifera with 5 samples.

How the data were processed

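Small RNA libraries were made from leaves of 5 in vitro grapevine plantlets, from total RNA extracted by a CTAB method and with a modified Illumina TruSeq small RNA kit, per the labels' protocols. Each deposited file held distinct sequences with their length and read count, per the file headers. The values were whole counts that were not normalized, and the authors had collapsed identical reads; the files held no sequence more than once and all lengths lay between 15 and 30 nt. FastQC is named in the submitters' processing notes. The adapter trimming, length filter and quality filter behind the counts are not given in the sources used here. A filter on length sets which RNAs can be seen, and no molecular identifiers were recorded, so counts include PCR copies.

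Each plant formed its own group with 1 library and 1 replicate number, taken from the sample titles. No test between plants was possible, and no p-value was computed. Shares are given with exact Clopper-Pearson 95% intervals and RPM (reads per 1000000 reads of the library) with exact Poisson 95% intervals, except that RPM of virus and viroid groups use the Clopper-Pearson bounds. Ratios of read numbers in the closing part use normal intervals on the log scale. A count of 0 was taken to allow 3 counts. Plans, thresholds and most alternatives were fixed before the data were examined. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, Biopython 1.88, BLAST+ 2.17.0 and programs written for the purpose and built with g++ 11.4.0.

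Mature miRNA sequences of 33 families (77 sequences) and the virus and viroid sequences used as queries were written down from general knowledge before the data were examined, not taken from a database; a wrong or missing sequence leaves reads uncounted. The families were assigned to lists for development, RNA silencing, nutrients, hormones, immunity, pigment and others. Reads identical to a listed sequence were summed per family and divided by all reads of the library. Families with a mean of at least 50 reads per library were compared with the median of the 5 plants on the log2 scale, and a value of 0 was replaced by 3 counts. A family stood apart at a log2 difference of at least 1 in size with Poisson intervals of that plant and the median plant that did not overlap. Families were named in the text by a fixed rule: all members of the silencing list, the 3 highest and 3 lowest families of each plant, and the 5 families of highest mean abundance. Other families were named where they alone made up a list, and miR482, the lone member of the immunity list that was compared, is among the highest 3 of Furmint1.

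No host genome was used here, so the planned shares of reads matching the host genome were not computed, and contigs were assembled from all reads of 20 to 24 nt, host reads included. Positions in the grapevine genome are therefore not given. Contigs were extended greedily where 17-nt words seen at least 2 times overlapped, with a look-ahead of 20 nt, and were kept from 60 nt. A contig was named by tblastn at 60% identity or more over at least 30 residues, by blastn at 80% or more over at least 50 nt, by a complete motif, or, for the apscaviroid-like group, as a closed circle with both conserved motifs. There were 6 protein queries (coat proteins of GRSPaV, GFLV, GVA and a trichovirus, and HSP70 homologues of leafroll-associated viruses 2 and 3) and 6 nucleotide queries and motifs. Contigs sharing most of their words were merged to 1, and reads of at least 18 nt were matched to them in full length without mismatch on either strand. A group was called detected where reads covered at least 50% of its contig positions. Small RNA coverage of RNA viruses is uneven, so the contigs are short parts of the genomes and RPM are those of the contigs, not of whole viruses. Ribosomal RNA reads were found with 3 sequences (5.8S, 18S and 25S) recalled after the data were seen, at up to 1 mismatch.

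Because few contigs of GRSPaV (grapevine rupestris stem pitting-associated virus) could be long enough, a second measure was added after the data were seen. Reads of 21 to 24 nt were translated, and a read counted where 7 codons in frame encoded 7 consecutive residues of a query protein; the same proteins read backwards served as control. For this measure sizes and strands were taken only from the window on the first 21 nt of a read, which every length has once. A replicase sequence of GRSPaV was added to the queries for it.

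The steps were tested on simulated data. In the library of Kékfrankos, an added circular RNA of 370 nt with 3000 reads was recovered as a closed circle with 100% of its reads, and an added coding RNA of 450 nt with 3000 reads was recovered in full. With 300 reads the coding RNA was detected with 19.3% of its reads counted and the circle was missed, and with 30 reads neither was found. The simulated reads were spread evenly, and the RNAs held the exact motifs or encoded the query protein itself. Recovery can thus be poorer in real data. Sarfeher1 had 83724 reads on the apscaviroid-like circle, yet only Furmint2 and the pooled reads gave such a circle. Absence of a contig therefore does not exclude an RNA, and not only at a low level. Each level was drawn once, and the share recovered at 300 reads depends on the draw. For the miRNA comparison, 201 of 201 simulated 2.5-fold changes and 199 of 199 simulated 4-fold changes in 1 plant against the median of 5 were found, and 0 of 4610 unchanged values stood apart. Each of the 50 simulated sets used the families that reached the minimum mean in it, 20 in the last set. These simulations had Poisson error only.

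The alternatives tried were each distinct sequence counted once, only sequences seen at least 2 times, miRNA reads recognised by their first 18 nt, the listed miRNA reads as denominator, a minimum mean of 10 reads, median-of-ratios size factors, 80% of positions covered, 1 mismatch, and reads of 20 to 24 nt as denominator. Added after the data were seen were size classes without listed miRNAs and ribosomal RNA, a denominator without miR166, the form shifted by 2 nt counted as miR166, contigs joined at 15 or 16 nt, and the GRSPaV replicase query.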

Results

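Small RNAs were profiled in leaves of 5 in vitro grapevine (Vitis vinifera) plantlets, named Kadarka, Sarfeher1, Furmint1, Kékfrankos and Furmint2. The series concerns chemotherapy, that is, antiviral drug treatment of plant cultures, as a means of freeing grapevine from viruses and viroids, and small RNA sequencing served to describe the virome of each plant. The labels gave no treatment for any library, so no treated plant was compared with an untreated one. Each plant was represented by 1 library without replicates, and the differences described below are therefore differences between 5 libraries with no replicate check. Furmint1 and Furmint2 carry the same cultivar name and were kept as separate plants.

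The files listed each distinct sequence of 15 to 30 nt with its read count. Kadarka had 14920395 reads over 2260732 distinct sequences, Sarfeher1 17868892 over 1063825, Furmint1 15302104 over 928413, Kékfrankos 14281449 over 749914 and Furmint2 16672006 over 1032926. Sequences read only once made up 66.5% of the distinct sequences in Kadarka and 63.8% in Furmint2, against 45.2%, 45.3% and 46.2% in Sarfeher1, Furmint1 and Kékfrankos. Of 5051841 distinct sequences found in any library, 49405 were found in all 5. At these depths a count of 0 allows up to 0.168 RPM (reads per 1000000 reads of the library) in Sarfeher1, the deepest library, and up to 0.210 in Kékfrankos, the shallowest. Intervals are exact 95% intervals (Clopper-Pearson for shares, Poisson for the RPM of miRNA families) and cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules.

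The first comparison asked which small RNA size classes the plants held. In plants, 21-nt small RNAs include most miRNAs and the siRNAs made from many viruses, 22-nt small RNAs include a class that can start secondary siRNA production, and 24-nt small RNAs come largely from transposons and repeats. The 21-nt class was the most abundant in every plant. It made up 46.0% of reads in Kadarka (interval 45.9 to 46.0), 47.8% in Sarfeher1 (47.8 to 47.8), 53.9% in Furmint1 (53.9 to 53.9), 63.6% in Kékfrankos (63.6 to 63.7) and 68.5% in Furmint2 (68.5 to 68.5). The 24-nt class ran the other way, with 22.6% of reads in Kadarka (22.5 to 22.6), 12.3% in Sarfeher1 (12.3 to 12.3), 10.3% in Furmint1 (10.3 to 10.3), 3.31% in Kékfrankos (3.30 to 3.32) and 2.46% in Furmint2 (2.45 to 2.47). The ratio of 21-nt to 24-nt reads thus went from 2.04 in Kadarka to 27.9 in Furmint2, and the 24-nt share differed 9.17-fold between these plants. The 22-nt share was highest in Furmint1 at 13.8% and lowest in Furmint2 at 7.36%.

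**Figure D1:**
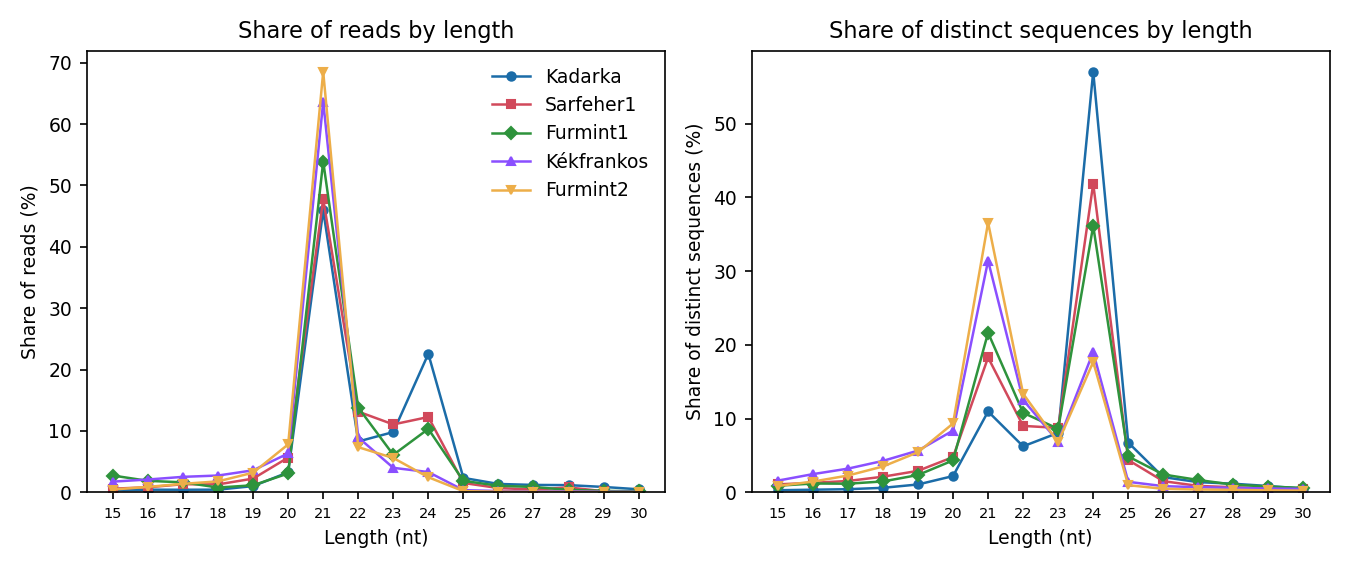
Share of reads (left, %) and of distinct sequences (right, %) at each length from 15 to 30 nt, with 1 line and symbol per plant. By reads, 21 nt was the peak in every plant and 24 nt reached 22.6% in Kadarka against 2.46% in Furmint2. By distinct sequences the peak was at 24 nt in Kadarka (57.1%), Sarfeher1 and Furmint1. In Kékfrankos and Furmint2 it stayed at 21 nt, with 31.4% and 36.6% against 19.03% and 17.7% at 24 nt.

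Counting each distinct sequence once narrowed the 24-nt difference between Kadarka and Furmint2 to 3.225-fold, from 57.1% to 17.7%. The most frequent first base of 24-nt reads was A, with 49.5% in Kadarka, 44.5% in Sarfeher1, 41.5% in Furmint1, 43.0% in Kékfrankos and 43.5% in Furmint2. The 21-nt reads began mostly with U, from 68.9% in Sarfeher1 to 84.5% in Furmint2. Among 21-nt reads of Sarfeher1, 24.5% began with C, and a 21-nt fragment of 25S ribosomal RNA, CCCAGTCCCGAACCCGTCGGC, alone made up 6.48% of that library. Reads matching ribosomal RNA made up 9.15% of reads of at least 18 nt in Kadarka, 15.7% in Sarfeher1, 6.65% in Furmint1, 9.70% in Kékfrankos and 9.17% in Furmint2, and 94.6% to 97.2% of them lay on the sense strand.

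The next comparison asked how the conserved miRNA families differed between the plants. Of 33 families listed, 20 had a mean of at least 50 reads per library and were compared with the median of the 5 plants. Reads identical to a listed mature miRNA made up 29.4% of reads in Kadarka, 21.2% in Sarfeher1, 35.9% in Furmint1, 43.0% in Kékfrankos and 43.5% in Furmint2. Most of them were miR166, which targets transcripts of class III HD-ZIP transcription factors, with 22.04% of all reads in Kadarka, 11.7% in Sarfeher1, 31.003% in Furmint1, 38.3% in Kékfrankos and 37.6% in Furmint2. In Sarfeher1 the most abundant sequence was TCTCGGACCAGGCTTCATTCC at 14.3% of reads, which overlaps the main miR166 sequence from 2 nt further upstream and was not in the list. The families of highest mean abundance after miR166 were miR3634, miR398, which targets copper/zinc superoxide dismutase transcripts, miR159, which targets GAMYB-like factors, and miR396, which targets growth-regulating factors. Their means over the 5 plants were 43353, 11379, 3287 and 2702 RPM.

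A family was taken to stand apart in a plant when it lay at least 2-fold from the median with separate Poisson intervals. By this rule 33 such differences were found. Of these, 7 were found under each of the 6 other settings of counting and scaling that were tried. Among those settings, the lower minimum mean cannot change a family already compared, and counting the shifted form alters miR166 alone. For the 7, none of which is miR166, only the remaining settings were therefore a check. These 7 were in 3 plants. In Furmint1, miR156, which targets SPL factors and marks the juvenile phase, was 3.40-fold the median at 643.9 RPM (interval 631.2 to 656.7), and miR482, which targets transcripts of NLR immune receptors, was 2.88-fold at 307.3 (298.6 to 316.2). On the log2 scale miR156 was at 1.76, but at 1.10 by the first 18 nt and at 1.00, the threshold, with the listed miRNA reads as denominator. Without miR166 in the denominator it was at 2.11. In the same plant miR319, which targets TCP factors, was at 0.270 of the median with 66.3 RPM (62.2 to 70.5), and miR395, which acts in sulfate assimilation, was at 0.101 of it with 0.392 (0.144 to 0.853), or 6 reads. In Sarfeher1, miR397, which targets laccase transcripts, was 3.98-fold the median at 96.9 RPM (92.4 to 101.5), and miR390, which starts the production of trans-acting siRNAs against auxin response factors, was at 0.308 of it with 25.2 (22.96 to 27.7). With the listed miRNA reads as denominator, miR397 moved from 1.99 to 3.01 on the log2 scale and miR390 from -1.70 to -1.01. Without miR166 in the denominator they were at 1.81 and -2.05. In Furmint2, miR535, related in sequence to miR156, was at 0.336 of the median with 31.1 RPM (28.5 to 33.9). On the log2 scale it was at -1.57, against -2.61 with the listed miRNA reads as denominator and -1.04 without miR166 in the denominator. The size of these differences therefore depends on the scaling.

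**Figure D2:**
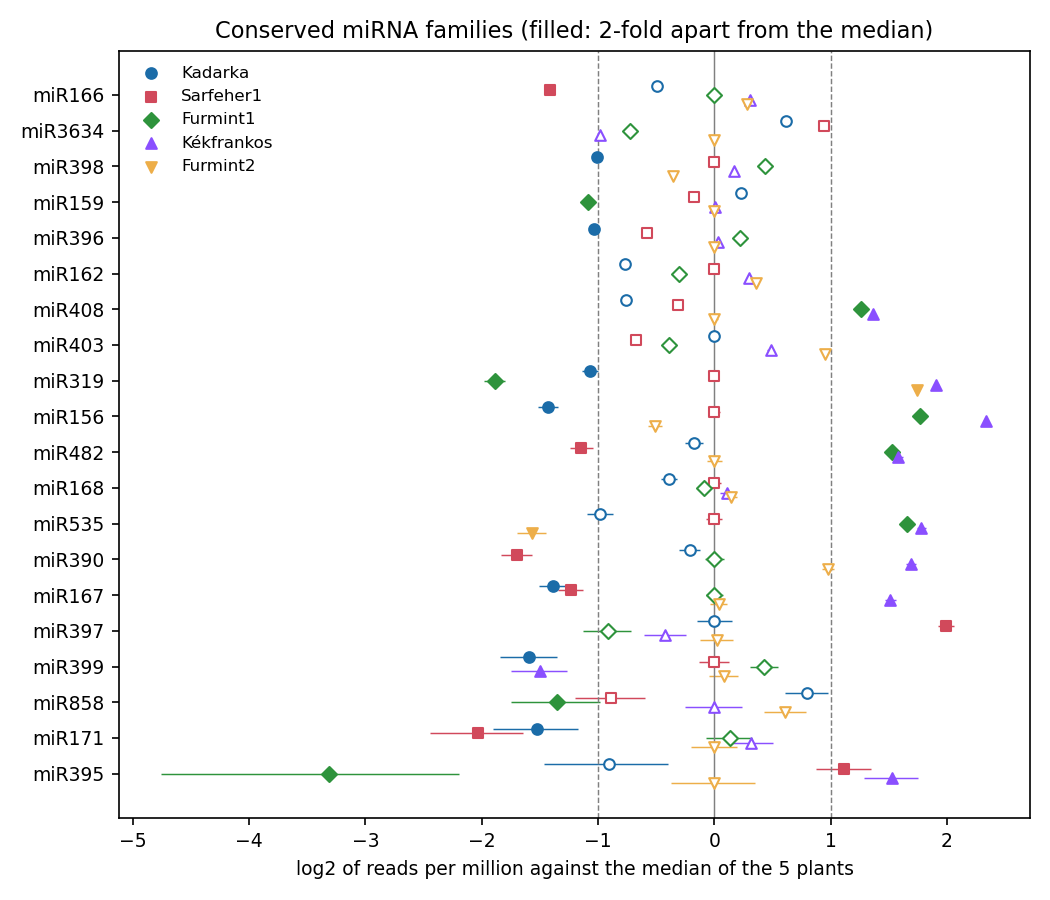
The log2 of RPM against the median of the 5 plants (horizontal axis) for the 20 families compared, ordered by mean abundance, with 1 symbol per plant, 95% Poisson intervals as bars and filled symbols for families at least 2-fold from the median with separate intervals. Furmint1 stands at -3.31 for miR395 and Kékfrankos at 2.33 for miR156, while miR162, miR168 and miR403 have open symbols in all 5 plants.

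By plant and with all reads as the denominator, 0 families were higher and 7 lower in Kadarka, 2 higher and 5 lower in Sarfeher1, 4 and 4 in Furmint1, 8 and 1 in Kékfrankos, and 1 and 1 in Furmint2. In Kékfrankos the largest differences were miR156 at 5.03-fold the median, miR319 at 3.75-fold and miR535 at 3.44-fold, and miR399, which acts in phosphate homeostasis, was at 0.353 of it. On the log2 scale miR156 was at 2.33 there, but at 0.943 by the first 18 nt. With size factors miR319 and miR535 fell from 1.91 and 1.78 to 0.796 and 0.670. Without miR166 in the denominator, miR156, miR319 and miR535 were at 2.84, 2.43 and 2.30. In Kadarka the lowest were miR399 at 0.331 of the median, miR171, which targets GRAS factors, at 0.347 and miR156 at 0.371. In Sarfeher1 the lowest included miR171 at 0.245 and miR166 at 0.377. The miR166 difference rested on the listed forms: with the form shifted by 2 nt counted as miR166, a setting chosen after seeing the data, it was at 0.774 of the median with 25.9% of reads. In the same plant miR395 was 2.17-fold the median. In Furmint1, miR535 was 3.15-fold the median and miR858, which targets MYB factors of the flavonoid pathway, was at 0.392 of it, and miR319 was 3.34-fold the median in Furmint2. Of the families of highest mean abundance, miR159 was at 0.471 of the median in Furmint1, and miR396 and miR398 were at 0.488 and 0.497 of it in Kadarka. Values of other families and plants selected by the naming rule were less than 2-fold from the median, among them miR858 at 1.73-fold and miR159 at 1.17-fold in Kadarka, miR3634 at 1.53-fold in Kadarka, 1.92-fold in Sarfeher1 and 0.507 in Kékfrankos, miR397 at 0.745 in Kékfrankos, and miR390 at 1.97-fold, miR403 at 1.94-fold, miR156 at 0.700 and miR398 at 0.782 in Furmint2.

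The RNA silencing list holds miR162, which targets Dicer-like transcripts, and miR168 and miR403, which target Argonaute transcripts. None of these 3 stood apart in any of the 5 plants with all reads as the denominator. This depended on the scaling for miR403 in Furmint2 and in Kadarka. Kadarka was the median plant with all reads as the denominator, but was past 2-fold with size factors. In Furmint2 miR403 was at 0.955 on the log2 scale. It was at 1.30 without miR166 in the denominator and at 1.004 with size factors, both past 2-fold. By the first 18 nt it was at 0.984, and with the listed miRNA reads as denominator at 0.455. The level of miR168 lay between 123.2 RPM in Kadarka and 178.3 in Furmint2, a 1.45-fold range, and those of miR162 and miR403 ranged over 2.19-fold and 3.10-fold. Of the 9 development families compared, 5 were lower in Kadarka, 4 were lower in Sarfeher1, 2 were higher and 2 lower in Furmint1, 5 were higher in Kékfrankos, and 1 was higher and 1 lower in Furmint2. Of the 5 nutrient families, 2 were lower in Kadarka, 2 were higher in Sarfeher1, 1 was higher and 1 lower in Furmint1, 2 were higher and 1 lower in Kékfrankos, and 0 of 5 stood apart in Furmint2. The immunity list had 1 family compared (miR482), which was higher in Furmint1 and Kékfrankos and lower in Sarfeher1, and the pigment list had 1 (miR858), which was lower in Furmint1. The list of other families had 1 compared, miR3634, and none of the 2 hormone families reached the minimum count.

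The counts of families depended on the scaling. The median family in Kadarka lay at -0.77 on the log2 scale against the median of the plants and that in Kékfrankos at 0.31, and median-of-ratios size factors moved these by 0.77 and -0.47. With those factors 4 families were higher and 0 lower in Kadarka, 1 was higher and 3 lower in Kékfrankos, and over all plants 15 were higher and 10 lower in place of 15 and 18. None of the 33 differences changed direction under any setting. Between pairs of plants, 7 to 13 of the 20 families differed at least 2-fold. Furmint1 and Furmint2, of the same cultivar name, differed in 9.

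The last comparisons asked which viruses and viroids left small RNAs in each plant. Contigs assembled from reads of 20 to 24 nt gave 4 named groups: an apscaviroid-like RNA, hop stunt viroid (HSVd), grapevine virus A (GVA, a vitivirus) and grapevine fanleaf virus (GFLV, a nepovirus). The apscaviroid-like RNA formed a closed circle of 368 nt with both conserved motifs of the genus Apscaviroid, whose members in grapevine include grapevine yellow speckle viroids; the species was not assigned. It was found in all 5 plants, with reads over 97.8% to 100% of its positions, although 50 of the 368 positions had at most 3 exact reads in Kadarka, against 14 in Furmint1 and 0 to 10 elsewhere. Its level was highest in Sarfeher1 at 4685 RPM (4654 to 4717), followed by Furmint2 at 2634 (2609 to 2659), Kékfrankos at 931.3 (915.6 to 947.3), Kadarka at 840.5 (825.9 to 855.4) and Furmint1 at 441.4 (430.9 to 452.0). Exact matching undercounts a diverged variant: with 1 mismatch allowed, Kadarka had 1092 RPM (1075 to 1109) and Kékfrankos 1113 (1096 to 1131), so the order of these 2 plants is not settled. The circle assembled from Furmint2 alone differed from the pooled one at 1 position.

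HSVd was represented by a contig of 283 nt that matched the viroid at 92.5% over 186 aligned positions. All of its positions were covered in 4 plants, with 2507 RPM in Sarfeher1 (2484 to 2530), 1675 in Kadarka (1654 to 1696), 1499.5 in Furmint2 (1481.0 to 1518.2) and 1332 in Kékfrankos (1313 to 1351). In Furmint1 it had 29 reads, or 1.90 RPM (1.27 to 2.72), over 60.4% of its positions. With contigs joined at 15 or 16 nt in place of 17, settings chosen after seeing the data, the HSVd contigs held 8784 and 8191 reads of Furmint1, of which 19 and 19 also matched the 283-nt contig; reads on these contigs that did not match the 283-nt contig came to 6352 to 15563 in the other plants. Over all reads on these contigs, of 1171 and 326 nt, the order of the 2 highest plants turned. Kadarka had 2250 RPM and Sarfeher1 2088 at 15 nt, and 2144 and 1929 at 16 nt. Among reads that also matched the 283-nt contig the order did not turn, with 1207 and 1464 RPM at both. Whether the remaining reads come from HSVd was not tested, so the totals are not taken as HSVd levels. GVA was found in Furmint2, where 4769 reads, or 286.0 RPM (278.0 to 294.3), covered all of a 164-nt contig whose translation matched the coat protein at 98.0% over 49 residues. GFLV was found in Furmint1, where 7501 reads, or 490.2 RPM (479.2 to 501.4), covered all of 2 contigs of 121 and 111 nt that matched the coat protein at 92.5% over 40 and 100% over 36 residues. The plants sharing the name Furmint thus differed in both viruses: Furmint2 had 1 read of GFLV and Furmint1 had 5 of GVA. Kadarka and Kékfrankos each had 1 read of GVA and 0 of GFLV, and Sarfeher1 had 0 of either, where a count of 0 allows 0.168 to 0.210 RPM. With contigs joined at 15 nt Furmint2 had 64 reads on the GFLV contigs and Furmint1 71 on the GVA contigs, of which 1 and 3 also matched the contigs joined at 17 nt, and at 16 nt they had 10 and 7, of which 1 and 4 did. At 15 nt the other 3 plants had 54 to 137 reads on the GFLV contigs and 11 to 53 on the GVA contigs, and at 16 nt they had 6 to 11 and 0 to 1; of these, 0 GFLV reads and at most 1 GVA read per plant also matched the contigs joined at 17 nt.

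**Figure D3:**
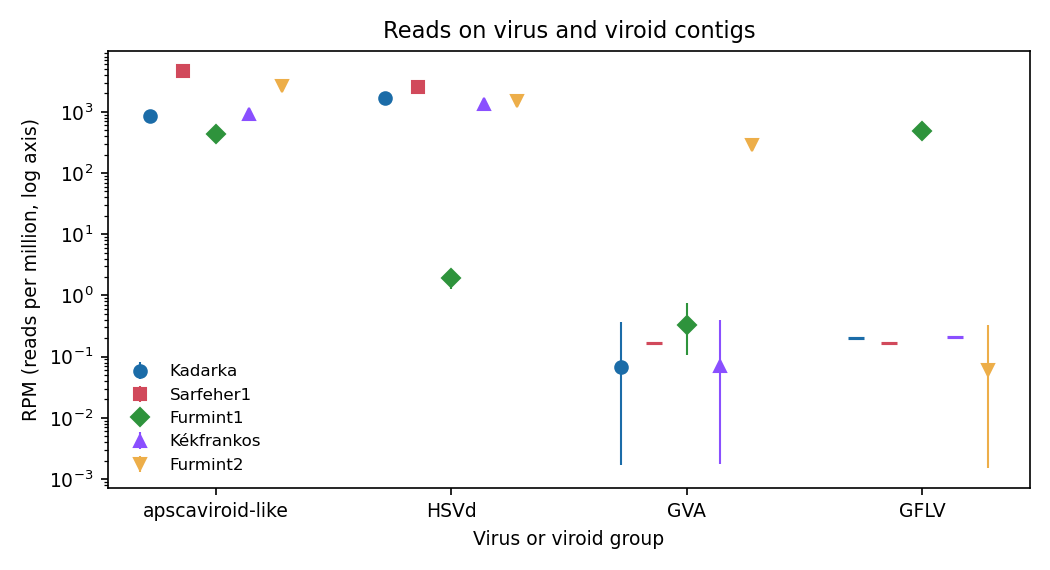
RPM (log axis) of reads that exactly match the contigs of each virus or viroid group, with 1 symbol per plant and exact 95% binomial intervals as bars; a dash marks 3 counts where 0 reads were found. The apscaviroid-like RNA lies between 441.4 and 4685 in all 5 plants, HSVd is at 1.90 in Furmint1 and at 1332 or more elsewhere, and GVA and GFLV exceed 1 RPM only in Furmint2 (286.0) and Furmint1 (490.2) respectively.

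By the fixed rule of at least 50% of positions covered, 2 groups were detected in Kadarka, 2 in Sarfeher1, 4 in Furmint1, 2 in Kékfrankos and 3 in Furmint2. The count for Furmint1 includes HSVd with 29 reads and GVA with 5 reads over 54.3% of positions, and both were lost when at least 80% of positions or sequences seen at least 2 times were required, which left 2 groups. The share of all reads from these groups was 0.719% in Sarfeher1 (0.715 to 0.723), 0.442% in Furmint2 (0.439 to 0.445), 0.252% in Kadarka (0.249 to 0.254), 0.226% in Kékfrankos (0.224 to 0.229) and 0.0934% in Furmint1 (0.0919 to 0.0949). In Furmint1 this share was 0.198% with contigs joined at 15 nt and 0.146% at 16 nt, settings chosen after seeing the data.

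The small RNAs of viruses and viroids had different sizes. Among GVA reads in Furmint2, 77.8% were of 21 nt, 16.1% of 22 nt and 0.147% of 24 nt (0.0590 to 0.302), and among GFLV reads in Furmint1 the shares were 72.3%, 19.8% and 1.79% (1.499 to 2.11). Of the apscaviroid-like reads, 42.4% were of 24 nt in Kadarka, 37.7% in Sarfeher1, 43.5% in Furmint1, 16.7% in Kékfrankos and 19.7% in Furmint2. HSVd reads of 24 nt made up 19.6% in Kadarka, 12.6% in Sarfeher1, 6.63% in Kékfrankos and 5.74% in Furmint2. In each of these 4 plants the 24-nt share was higher for the apscaviroid-like RNA than for HSVd, with intervals that did not overlap. The first base of reads on the virus contigs was mostly U, at 59.7% for GVA in Furmint2 and 63.5% for GFLV in Furmint1. This did not hold for translated windows over more of the coat proteins, which take reads in 1 frame per strand: there U made up 43.7% for GVA, and 28.2% for GFLV against 41.8% for C. Viroid reads began most often with C, at 39.4% to 54.0% for the apscaviroid-like RNA and 54.6% to 63.3% for HSVd in the 4 plants above 1000 reads.

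**Figure D4:**
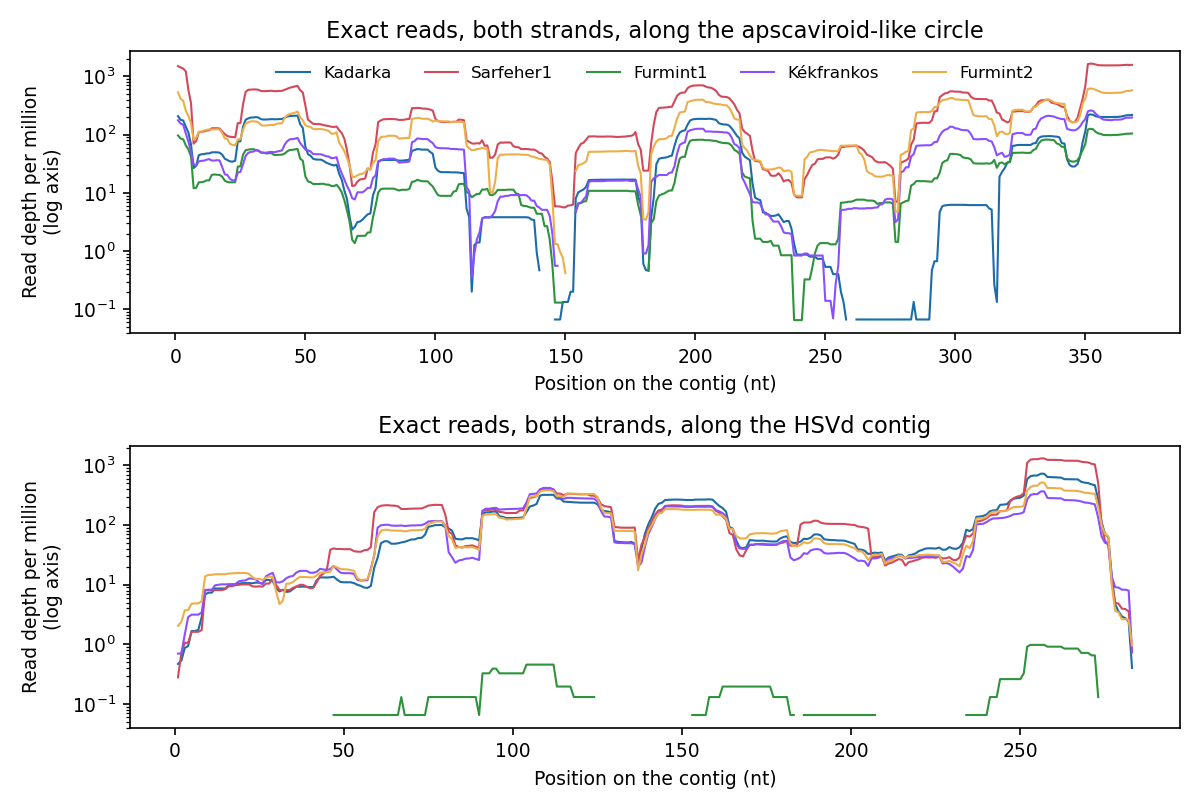
Depth of exactly matching reads in RPM (log axis) along the 368-nt apscaviroid-like circle (top) and the 283-nt HSVd contig (bottom), both strands summed, with 1 line per plant; gaps are positions with 0 reads. On HSVd the lines of 4 plants run close together and that of Furmint1, with 29 reads, lies far below them.

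Both strands contributed in every group. Sense reads made up 34.3% of GVA reads in Furmint2 (33.0 to 35.7) and 43.6% of GFLV reads in Furmint1 (42.4 to 44.7), against 21.2% (19.8 to 22.7) and 42.8% (41.8 to 43.8) by translated windows of the coat proteins. They made up 40.5% (Sarfeher1) to 54.3% (Furmint2) of HSVd reads in the 4 plants with over 1000 of them. On the apscaviroid-like circle, whose strands were named by its conserved motifs, the corresponding share was 43.1% in Kadarka and 56.7% in Furmint2. The conserved motifs of marafiviruses and tymoviruses had 0 reads in each plant. A motif of HSVd counted in the same way had 0 to 7 reads although 4 plants had 19025 to 44797 HSVd reads, so these viruses are not excluded. With contigs joined at 17 nt and the queries fixed at the start, no contig met the naming rule for grapevine leafroll-associated viruses 2 and 3, for a trichovirus or for grapevine rupestris stem pitting-associated virus (GRSPaV). Under settings chosen after seeing the data, GRSPaV was detected in Kadarka, Sarfeher1 and Furmint1 at 15 nt and in Kadarka and Furmint1 with an added replicase query, and a contig passing the rule for leafroll-associated virus 3 was detected in Kadarka and Furmint2 at 16 nt. The 3 longest contigs without a name, of 1048, 929 and 654 nt, matched 25S ribosomal RNA at 97.6%, 95.3% and 98.0% identity.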

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

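No paired analysis was possible because each plant is a group of 1 library, and for the same reason no library was left out in turn. The host genome match shares and their 2 alternatives were not run, since no host genome was used here. Size classes without miRNAs and ribosomal RNA, the denominator without miR166, the shifted form counted as miR166, contigs joined at 15 or 16 nt and the GRSPaV query were chosen after seeing the data. Of 140 values for size classes, family counts, detections and read shares under another setting, 68 stayed (shares within their 95% interval, counts within 1.5 times, so that 2 and 3 groups are counted alike) and 72 moved; the cause was not tested unless the setting itself gives it. The intervals of shares cover counting error only and are narrow, such as 45.93 to 45.98% for 21 nt in Kadarka. A share that moved may therefore have changed little, and these counts do not measure how much. Of 180 log2 values of named families, 85 stayed and 95 moved, and 0 of those that stood apart changed direction. Of the 85, 30 were under the minimum mean of 10 reads, which cannot change the value of a family already compared. Another 29 were under the shifted form, which alters miR166 alone. With size factors 1 of 30 stayed, with the listed miRNA reads as denominator 4 of 30, without miR166 in the denominator 4 of 30, and by the first 18 nt 17 of 30. Depth limited families near 50 reads and contigs with few reads.

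In the order Kadarka, Sarfeher1, Furmint1, Kékfrankos and Furmint2, the 21-nt share was 10.97, 18.3, 21.6, 31.4 and 36.6% with distinct sequences counted once, 49.9, 48.5, 54.7, 64.4 and 69.9% with sequences seen at least 2 times, and 32.6, 40.5, 33.1, 43.0 and 55.7% without listed miRNAs and ribosomal RNA. The 24-nt share in the same order was 57.1, 41.9, 36.2, 19.03 and 17.7%, 18.9, 11.6, 9.78, 2.97 and 1.82%, and 35.9, 18.7, 16.7, 6.54 and 4.96%. Kadarka was highest and Furmint2 lowest for 24 nt in all of these. For 21 nt Furmint2 was highest in all of them, and Sarfeher1 was lowest when only sequences seen at least 2 times were kept.

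With the listed miRNA reads as denominator, 2 families were higher and 4 lower in Kadarka, 1 was lower in Sarfeher1, 2 were higher in Furmint1, 5 were higher in Kékfrankos, and 0 were higher and 2 lower in Furmint2. With size factors, 4 were higher and 0 lower in Kadarka, 2 were lower in Furmint1, 1 was higher and 3 lower in Kékfrankos, and 3 were higher in Furmint2. A minimum mean of 10 reads gave 1 higher in Kadarka and 4 in Furmint2, the first 18 nt gave 3 higher and 2 lower in Furmint2, and leaving miR166 out of the denominator gave 1 higher in Sarfeher1, 0 lower in Kékfrankos and 3 higher in Furmint2. All 7 differences of Kadarka and all 9 of Kékfrankos were lost under at least 1 setting.

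In Furmint1, 2 groups in place of 4 were detected at 80% of positions and 2 with sequences seen at least 2 times. Contigs joined at 15 nt gave 3 groups in Kadarka, 3 in Sarfeher1 and 3 in Furmint1, with GRSPaV gained in each, and GVA and HSVd lost in Furmint1. At 16 nt there were 3 in Kadarka and 4 in Furmint2, with grapevine leafroll-associated virus 3 gained by the naming rule, and 3 in Furmint1, where GVA was lost. The GRSPaV query gave 3 in Kadarka and 5 in Furmint1, with GRSPaV gained. The share of virus and viroid reads, in the same order of plants, was 0.305, 0.800, 0.108, 0.258 and 0.494% with 1 mismatch, 0.273, 0.781, 0.105, 0.258 and 0.474% of reads of 20 to 24 nt, 0.311, 0.679, 0.198, 0.257 and 0.514% with contigs joined at 15 nt, and 0.299, 0.661, 0.146, 0.249 and 0.520% at 16 nt. Sarfeher1 was highest and Furmint1 lowest in all of these. At 15 and 16 nt the HSVd contigs grew to 1171 and 326 nt, and reads of Furmint1 on them rose from 29 to 8784 and 8191, which covered 48.8% and 64.4% of positions; 19 and 19 of them also matched the contig joined at 17 nt.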

Other observations

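The measure by translated windows and the tests of the 24-nt share without abundant sequences, of a length range as its whole cause and of a single carry-over rate, and the deletion rates without sequences of the miR166 core, were chosen after the results were seen. Reads encoding parts of GRSPaV, a foveavirus common in grapevine, were present in all 5 plants. Of 2408 windows of its coat protein and replicase, 41.0% were matched in Kadarka, 27.1% in Furmint2, 15.4% in Sarfeher1, 12.2% in Furmint1 and 8.39% in Kékfrankos, while the backward proteins were matched in 1.70%, 0.457%, 0.789%, 0.540% and 0.374% of windows. Matching reads came to 482.8 RPM in Kadarka (471.7 to 494.0), 308.8 in Sarfeher1, 221.1 in Furmint2, 169.9 in Furmint1 and 83.5 in Kékfrankos (78.9 to 88.4). A longer read has more places to match, so these RPM and window shares favour plants with longer reads, such as Kadarka. By the first window alone there were 4190 reads in Kadarka, 3644 in Sarfeher1, 2969 in Furmint2, 1679 in Furmint1 and 1007 in Kékfrankos. The order was the same, with smaller differences from Kadarka. Windows count only reads that keep the residues of the query, so a diverged strain is undercounted. Sense reads made up 42.8% (Kékfrankos) to 57.9% (Sarfeher1) of them, and 21-nt reads 43.2% (Kadarka) to 71.7% (Furmint2). The same measure matched 46.6% of GFLV coat protein windows in Furmint1 and at most 1.205% elsewhere, and 59.4% of GVA coat protein windows in Furmint2 and at most 1.04% elsewhere.

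Furmint2 also had 898 reads encoding windows of the HSP70 homologue of grapevine leafroll-associated virus 3, over 2.23% of its windows, against 111 reads over 4.47% in Kadarka and 3 to 23 in the other plants. Of these reads in Furmint2, by the first window, 74.4% were of 21 nt and 25.1% of 22 nt, and 62.4% were sense, whereas 86.1% were sense in Kadarka. When contigs were joined at 16 nt, a 113-nt contig passed the naming rule for this protein, with 2614 reads over all of its positions in Furmint2 and 85 reads over 68.1% in Kadarka. It had 1 read in Furmint1, 0 in Sarfeher1 and 0 in Kékfrankos. The backward protein was matched in 0.556% of windows in Furmint2 and 0.741% in Kadarka. For the HSP70 homologue of leafroll-associated virus 2, 1.86% of windows were matched in Furmint2, 2.03% in Kadarka and 1.52% in Sarfeher1. In Furmint1 and Kékfrankos 0.338% were matched. The breadth in Furmint2 was thus near that of the other HSP70 query. HSP70 proteins of plants share residues with the viral homologue, and neither the virus nor a host origin was assigned.

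The 24-nt share, highest in Kadarka and lowest in Furmint2, was weighed first. A dilution of 24-nt reads by a few abundant 21-nt sequences is argued against, since the share still differed 7.25-fold without listed miRNAs and ribosomal RNA. A different length range kept at library preparation may be part of the cause: among sense fragments of ribosomal RNA, without the 10 most abundant, the ratio of 24-nt to 21-nt reads was 6.67 times higher in Kadarka than in Furmint2 (6.54 to 6.80), against 4.16 times with all sense fragments and 3.58 times with each distinct fragment counted once. Furmint1 does not follow this: its ratio among these fragments without the 10 most abundant, 0.961, was above the 0.700 of Kadarka, while among reads outside miRNAs and ribosomal RNA it was 0.504 against 1.10. Kadarka also had larger shares than Furmint2 at every length from 25 to 30 nt. At 25 nt they were 2.35% against 0.190% of reads, and at 28 nt 1.17% against 0.0706%. From 15 to 19 nt its shares were smaller, with 1.01% against 3.20% at 19 nt. The whole length profile was thus shifted between these 2 plants. A length range is argued against as the whole cause, since the factor for reads outside miRNAs and ribosomal RNA, 12.4, was 1.86 times larger, and the factors for the apscaviroid-like RNA, HSVd and GRSPaV windows were 4.07, 4.81 and 16.98 where a length range alone would give 1 factor to all. What stays open is a difference in 24-nt siRNA production between the plants, which was not tested, and RNA quality.

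The 29 HSVd and 5 GVA reads of Furmint1 on the contigs joined at 17 nt could be carry-over from other libraries. The 8784 and 8191 reads on HSVd contigs joined at 15 and 16 nt were not part of these tests, since only 19 and 19 of them also matched the 283-nt contig, and what the others come from was not tested. A single rate for all markers was judged only by overlap of intervals. Pooled over the plants with few reads of each marker, HSVd came to 25.5 reads per 100000 in the other plants (17.1 to 36.6). GVA came to 36.7 (14.8 to 75.6) and GFLV, with 1 read, to 3.33 (0.0844 to 18.6). These intervals overlap, as do the 9 intervals of single plants. Overlap does not test whether rates are equal, and the HSVd value lay above the whole GFLV interval. A single rate is thus left undecided. Carry-over in proportion to abundance stays open as well, because all 29 HSVd reads had sequences present in other plants and their 18 distinct sequences lay at the edge of the central 95% of 10000 random draws from those plants (18 to 26). A low level of HSVd in Furmint1 itself would draw on the same sequences and was not separated from it.

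Sequences equal to the main miR166 sequence with 1 inner base left out were more frequent in Furmint2, with 23.3 per 1000 miR166 reads against 5.17 in Kadarka, 9.40 in Sarfeher1, 2.33 in Furmint1 and 2.46 in Kékfrankos. A single form, TCGGACCAGGCTTCATCCCC, made up 84.7% of them in Furmint2, 54.3% in Kadarka, 70.6% in Sarfeher1, 52.8% in Furmint1 and 32.05% in Kékfrankos. That form also equals the main sequence with 1 T changed to C and the last base lost. Whether a base was deleted is therefore not established. A higher deletion error throughout that library is argued against, since over 29 other abundant sequences the median rate in Furmint2 was 1.24 times the median of the other plants. Since some of these are themselves forms of miR166, the 21 without its core GGACCAGGCTTCAT were also taken alone: 0 of them had a rate in Furmint2 at least 2 times the median of the other plants, and their median ratio was 1.12. Of the 8 with the core, 4 did, with a median ratio of 3.59, but part of these restate the miR166 values. The origin of these forms, whether an error at this sequence or a transcribed variant, was not tested.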
